A study of Mus musculus with 3 samples.

How the data were processed

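H3K4me3, a histone mark found at the start sites of active genes, was profiled by chromatin immunoprecipitation and sequencing in 3 libraries of male germ cells from adult C57BL/6J mouse testes. The testes were dissociated with collagenase and trypsin, the chromatin was digested with micrococcal nuclease (MNase), and the immunoprecipitation used 1 H3K4me3 antibody for all libraries, per the labels' protocols. Micrococcal nuclease cuts between nucleosomes and has sequence preferences of its own, which can move counts between promoters. The libraries came from leptotene/zygotene spermatocytes (LZ), pachytene/diplotene spermatocytes (PD) and elongating spermatids (ES), with 1 library for each stage. Groups were taken from the cell type label, and each column of the table was matched to its library by the description label.

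The deposited table holds raw counts, not normalized, for 11140 promoters in the 3 libraries. Trim Galore, STAR and the mm10 genome build are named in the submitters' processing notes, without versions. STAR aligns reads with gaps by default, and whether that was switched off for genomic DNA is not given in the sources used here. Whether the ES library was processed in the same way as the others, the counting tool, the handling of duplicate and multiply mapped reads, the placement of the window relative to the start site and the choice of the promoters listed are not given in the sources used here either. All 11140 rows carry an identifier of an assembled locus, numbered between 1 and 27289, and the files do not pair these with gene names or coordinates. Matching them to gene symbols, synonyms and accessions of a mouse RefSeq gene table (GRCm38.p6) gave 0 matches. Levels by gene, gene list and chromosome are therefore not analysed here. Before the data were examined, 20 gene lists, a comparison of X-linked with autosomal promoters and a scaling to housekeeping genes had been planned, and none of these could be run.

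The totals were 1654906 counts in LZ, 4826890 in PD and 17989325 in ES. They sum the promoters in the table and not the whole libraries, whose sequencing depth is not given in the sources used here. Levels in CPM, the counts per 1000000 counts of a library, were computed from these totals, so a level is a share of the counts over these promoters, and a change of H3K4me3 common to all promoters cannot be seen. A count of 0 allows up to 3 counts, which is 1.81 CPM in LZ, 0.622 CPM in PD and 0.167 CPM in ES. Intervals of single promoters are exact 95% intervals (Poisson for a level, Clopper-Pearson for a share or for the ratio of counts between libraries). Clopper-Pearson intervals of a percentage of promoters treat promoters as independent. Neighbouring loci had weakly correlated marking, so those intervals may be too narrow. Intervals of single promoters, floors and comparisons of randomly divided or thinned counts cover at most counting error. They may understate it, since reads made by PCR without molecular identifiers are not independent molecules.

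With 1 library per stage there is no test between stages and no p-value. edgeR's and DESeq2's tests were not run for that reason. A promoter was counted as higher or lower by a rule of size fixed before the data were examined. It needed a ratio of at least 2 either way, with 1 count added in proportion to library size, and at least 20 counts in the higher of the libraries compared. These counts describe the 3 libraries. Checked on simulated Poisson counts for 11140 promoters with 200 of them changed by 4-fold, the rule recovered 99.4% of the changed promoters that reached the minimum count for PD against LZ, 100.0% for ES against PD and 100.0% for ES against LZ. It wrongly counted 1.85%, 0.165% and 0.568% of the unchanged promoters that reached the minimum count, in the same order. The simulated changes were few, as many up as down, and larger than the 2-fold threshold, so high recovery was built in. Variation between animals, cell preparations and immunoprecipitations was not part of that simulation and would add to the wrongly counted promoters. Uncertainty in the scaling between libraries was not part of it either, so these percentages do not measure performance on the 3 libraries.

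LZ and PD counts were each split into a low and a high group at the point of equal probability of a 2-component normal mixture fitted to log2(count + 1). This split, the comparison of 1 stage with both others, and the sets based on the highest or lowest part of a library were chosen after the data were seen. The identifiers named were to be the 10 highest and 10 lowest per comparison, ranked by the bound of the ratio's interval nearest to 1. As identifiers without gene names say little, only the first in each direction is named for PD against LZ and for ES against PD. The promoter with the most counts was named after its values were seen.

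Alternatives planned before the data were examined were TMM factors (edgeR 4.0.16), median-of-ratios size factors (DESeq2 1.42.0), thinning to the smallest total, a minimum of 50 counts or none, an added count of 0.25 or 5, and a 4-fold threshold. Those added afterwards were quantile normalization, subtraction of a background taken from the 10% of promoters with the lowest mean CPM, scaling to the low or to the high promoters of LZ and PD, and leaving out the most counted promoter or the last 140 rows. Computations used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9, and R 4.3.3.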

Results

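The data describe H3K4me3 at 11140 promoters in 3 stages of mouse spermatogenesis, in order of development but not adjacent throughout. Leptotene/zygotene spermatocytes (LZ) are cells in early meiotic prophase, in which chromosomes pair. Pachytene/diplotene spermatocytes (PD) follow, with fully paired and then separating chromosomes. Elongating spermatids (ES) are haploid cells after meiosis, in which histones are exchanged for protamines. Each stage was measured in 1 library, so differences between stages carry no replicate check. The promoter counts summed to 1654906 in LZ, 4826890 in PD and 17989325 in ES.

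The 3 libraries had different distributions of H3K4me3 over the promoters. In LZ and in PD, promoters fell into a low and a high group. The low group was centred at 16.7 counts in LZ and the high group at 254 counts. In PD the centres were 18.5 and 718 counts. On the scale of count + 1, on which the groups were fitted, the centres were 14.4-fold apart in LZ and 36.9-fold apart in PD. The low group held 55.4% of the promoters in LZ and 58.7% in PD. The ES library had 1 broad peak with a shoulder on its upper side, and its lowest promoter had 8 counts. After all libraries were thinned to 1654906 counts, the 10th percentile was 8 counts in LZ, 2 in PD and 15 in ES, and the median was 56, 20 and 80 counts. The 90th percentile, at 422 counts in LZ, 526 in PD and 404 in ES, differed less. As no input library was analysed here, the 10% of promoters with the lowest mean level served as background. Their median was 5.44 CPM in LZ, 1.66 CPM in PD and 8.39 CPM in ES. The 90th percentile lay above this background by 46.9-fold in LZ, 192-fold in PD and 29.1-fold in ES. This background is the lower end of the same libraries, so these folds describe spread and do not measure enrichment. They lie near the ratios of the 90th to the 10th percentile, at 52.8 in LZ, 219 in PD and 26.6 in ES.

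**Figure D1:**
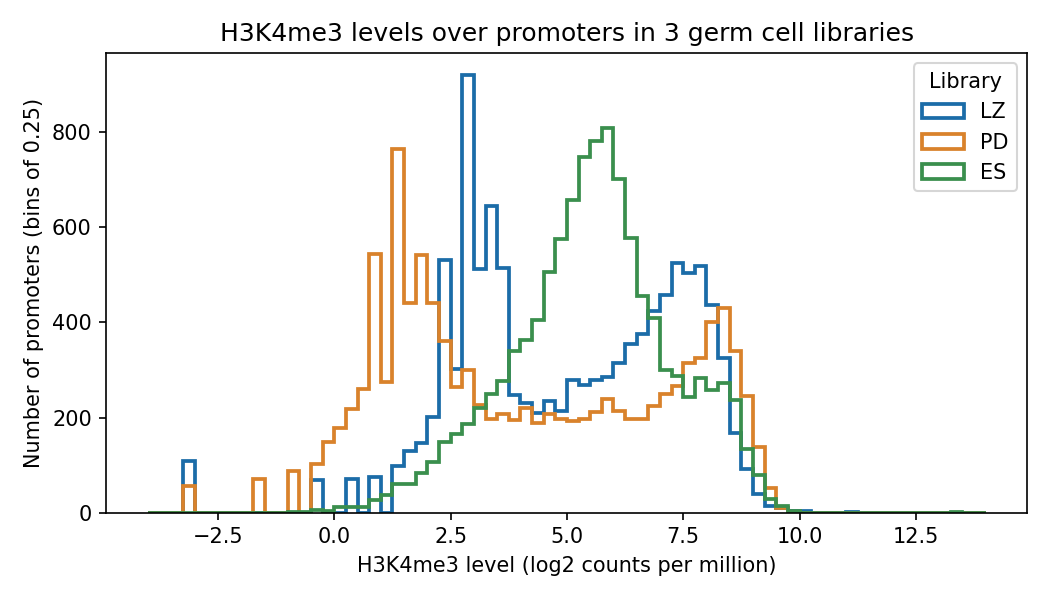
Number of promoters (vertical axis, bins of 0.25) at each H3K4me3 level (horizontal axis, log2 CPM) in the LZ, PD and ES libraries. LZ and PD each show a low and a high group of promoters, and ES shows 1 broad peak with an upper shoulder.

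The first comparison was between early and mid to late meiotic prophase. Most promoters kept their group from LZ to PD. The high group of both libraries shared 3756 promoters and the low group of both shared 5331, while 1211 promoters were high in LZ only and 842 in PD only. Promoters high in both had a median of 185 CPM in LZ and 211 CPM in PD. Promoters high in LZ only had medians of 92.5 CPM in LZ and 10.4 CPM in PD, and those high in PD only had 19.9 CPM in LZ and 74.0 CPM in PD. Ranks correlated across promoters with a Spearman rho of 0.78 and a Pearson r of 0.78 on log2 CPM. Promoters are not independent replicates, so these coefficients describe the 2 libraries compared.

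By the rule of size, 1332 promoters were at least 2-fold higher in PD than in LZ and 3391 were at least 2-fold lower, of 8286 with enough counts. Of the lower promoters, 1211 were the group high in LZ only, 706 were high in both and 1474 were low in both. Of the higher promoters, 675 were high in PD only, 506 were high in both and 151 were low in both. The classes and the ratio rest on the same LZ and PD counts. The boundary, set on counts and not on CPM, was 82.9 counts in LZ and 136 in PD. All promoters high in LZ only were counted as lower in PD, almost by definition. Of those high in PD only, 80.2% were counted as higher, and the others were not 2-fold apart. The balance of higher against lower depended on the scaling. The median log2 ratio of PD to LZ over all promoters was -0.99 with library totals, -0.29 with TMM factors and 0.15 with median-of-ratios size factors. With library totals, the median was 0.12 for promoters high in both and -1.51 for those low in both. It was -3.25 for those high in LZ only and 2.20 for those high in PD only. With library totals, promoters high in both thus did not share the overall shift. These totals rest mostly on highly counted promoters. Promoters at or below the median count held 5.88% of the LZ counts and 2.03% of the PD counts. When scaled to promoters low in both, 4241 promoters were higher in PD and 1595 were lower. Whether low promoters fell or high promoters rose cannot be told from these shares. Lower promoters made up 71.8% of those counted with library totals, 48.7% with TMM factors, 35.6% with median-of-ratios size factors and 49.9% with quantile normalization. Of the 3391 lower promoters, 2536 were also lower with TMM factors, 2021 with median-of-ratios factors and 1782 with quantile normalization. Of the 1332 higher promoters, 1268 were also higher with quantile normalization. TMM and median-of-ratios factors shift all ratios of PD to LZ upward together, so they could not remove a higher promoter.

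The first-ranked promoter in each direction belonged to locus MSTRG.6179, which was higher in PD, and to locus MSTRG.20916, which was lower. MSTRG.6179 had 13 counts in LZ and 2247 in PD, or 7.86 CPM (95% interval 4.18 to 13.4) and 466 CPM (446 to 485). Its ratio was 59.3 by the counts alone (interval 34.6 to 111). With the added count, the log2 ratio of PD to LZ at MSTRG.6179 was 5.87 with library totals and ranged from 5.33 with quantile normalization to 7.51 after background subtraction, with 7.05 for median-of-ratios factors. MSTRG.20916 had 1448 counts in LZ, 11 in PD and 81 in ES, or 875 CPM (830 to 921), 2.28 CPM (1.14 to 4.08) and 4.50 CPM (3.58 to 5.60). The level in LZ was 384 times that in PD by the counts alone (interval 214 to 771). With the added count, the log2 ratio of PD to LZ was -8.51 with library totals, -7.37 with median-of-ratios factors, -6.54 with quantile normalization and -10.19 after background subtraction. The direction from PD to ES at MSTRG.20916 depended on the scaling, with a log2 ratio of 0.95 with library totals, -0.33 with median-of-ratios factors, -1.69 with quantile normalization and -2.60 after background subtraction. The intervals cover at most counting error and not the choice of scaling. They also do not allow for the selection of these promoters by the same intervals, so the ratios may be too extreme.

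The second comparison set elongating spermatids against spermatocytes in pachytene/diplotene, across the meiotic divisions and the stages in between, which were not sampled. The ES profile correlated weakly with the PD profile: the Spearman rho across promoters was 0.21, and the Pearson r on log2 CPM was 0.21. The rho was 0.32 within promoters high in both LZ and PD and 0.09 within those low in both. By the rule of size, 5806 promoters were at least 2-fold higher in ES than in PD and 3298 were lower, of 11121 with enough counts. Of the higher promoters, 4583 were low in both LZ and PD and 915 were high in LZ only. Of the lower promoters, 2578 were high in both and 550 were high in PD only. PD counts enter both the class and the ratio here, which by itself places low promoters among the higher ones. The median log2 ratio was 1.25 with library totals, 0.82 with TMM factors and -0.05 with median-of-ratios size factors. Higher promoters made up 63.8% of those counted with library totals, 49.6% with median-of-ratios factors and 43.6% with quantile normalization.

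**Figure D2:**
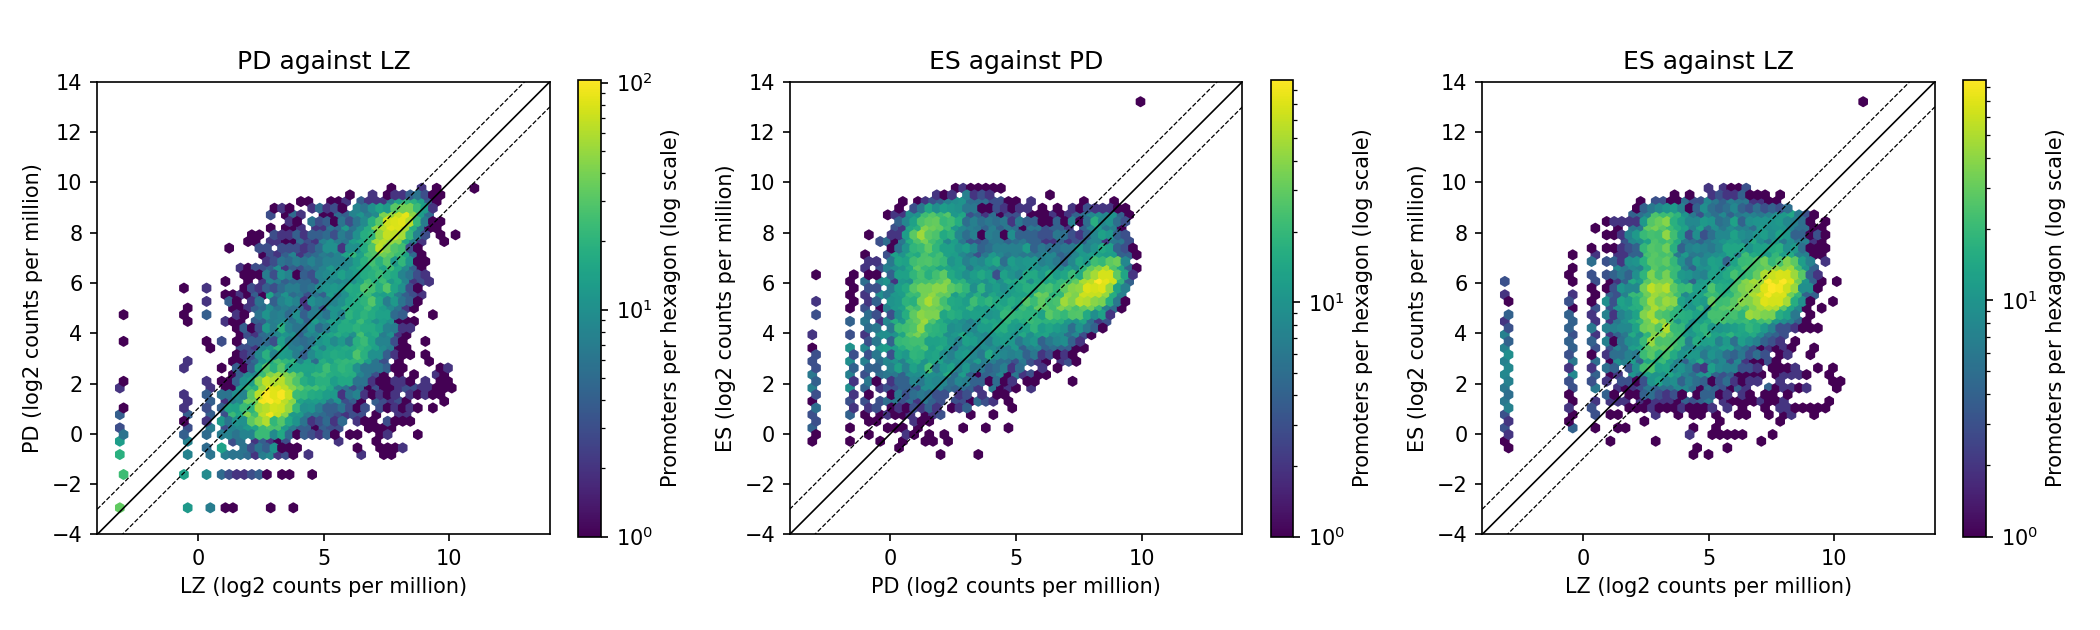
H3K4me3 levels of the 11140 promoters in each pair of libraries (both axes log2 CPM), coloured by the number of promoters per hexagon on a log scale. The solid line marks equal levels and the dashed lines mark a 2-fold difference. PD and LZ levels rise together (Spearman rho 0.78) with most promoters below the line of equal levels, while ES spreads widely at promoters low in PD or LZ (0.21 and 0.22).

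The ES counts, which took no part in defining the classes, ordered them differently from LZ and PD. The median ES count was 1079 for promoters high in both spermatocyte libraries, 825 for those high in LZ only, 585 for those high in PD only and 695 for those low in both. Promoters high in both exceeded those low in both by 1.55-fold in ES, against 21.9-fold in LZ and 72.7-fold in PD, where the counts define the classes. The spread within a class was wide. Among promoters low in both, the 10th and 90th percentiles of the ES count were 110 and 5096, and among those high in both they were 486 and 3111.

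The most strongly marked promoters of ES were more often low than high in spermatocytes. The top 10% of ES comprised 1114 promoters with at least 4389 counts. Of these, 683 (61.3%) were low in both LZ and PD, a class that made up 47.9% of all promoters, and 245 (22.0%) were high in both, a class of 33.7%. Within classes, 12.8% of promoters low in both reached the ES top 10% (95% Clopper-Pearson interval 11.9 to 13.7), as did 13.05% of those high in LZ only (11.2 to 15.1). For promoters high in both the share was 6.52% (5.75 to 7.36), and for those high in PD only it was 3.33% (2.22 to 4.77). These intervals treat promoters as independent. The ES top 10% had a median of 6255 counts in ES, 35 in LZ and 25 in PD, while all other promoters had medians of 766, 60 and 71. This ranking within each library does not depend on the scaling between libraries.

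**Figure D3:**
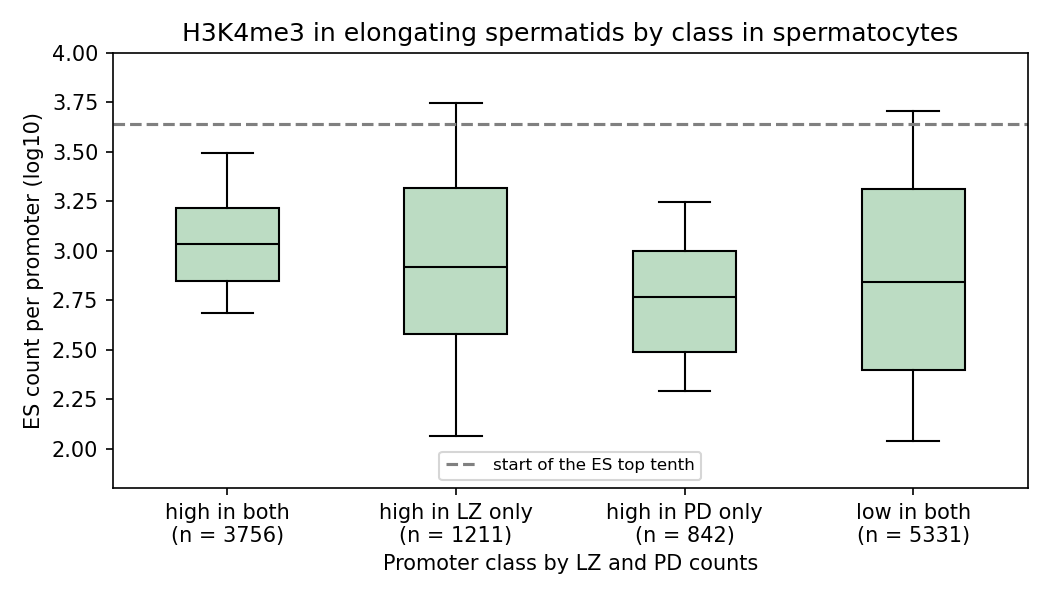
ES counts per promoter (vertical axis, log10) for the 4 classes of promoters set by LZ and PD counts (horizontal axis, with the number of promoters). Boxes show the quartiles and the median, whiskers the 10th and 90th percentiles, and the dashed line the start of the ES top 10% at 4389 counts. Class medians lie between 585 and 1079 counts, and the upper whisker passes the dashed line for promoters low in both and for those high in LZ only.

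The first-ranked promoter in each direction between PD and ES belonged to loci MSTRG.25815 and MSTRG.12373. MSTRG.25815 had 11 counts in LZ, 6 in PD and 10189 in ES, and its ES level of 566 CPM (555 to 577) was 456 times the PD level by the counts alone (interval 209 to 1242). With the added count, the log2 ratio of ES to PD at MSTRG.25815 was 8.70 with library totals, 7.45 with median-of-ratios factors, 7.03 with quantile normalization and 12.15 after background subtraction. MSTRG.12373 had 107 counts in LZ, 744 in PD and 77 in ES. Its PD level of 154 CPM (143 to 166) was 36.0 times the ES level of 4.28 CPM by the counts alone (interval of the ratio 28.5 to 46.1). With the added count, the log2 ratio of ES to PD at MSTRG.12373 was -5.13 with library totals, -6.44 with median-of-ratios factors, -5.74 with quantile normalization and -10.28 after background subtraction. Where background subtraction leaves a level at 0, the ratio rests on the added count. The ratio intervals of MSTRG.25815 and MSTRG.12373 likewise do not allow for their selection as first-ranked. The promoter with the most counts in each of the 3 libraries was that of locus MSTRG.24815. It took 0.216% of the LZ counts (0.209 to 0.223), 0.0942% of the PD counts (0.0915 to 0.0970) and 1.03% of the ES counts (1.03 to 1.04). Its 185534 counts in ES compare with 16289 for the next promoter.

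Between ES and LZ, the earliest and latest stages, the Spearman rho across promoters was 0.22 and the Pearson r on log2 CPM was 0.24. By the rule of size, 4474 promoters were at least 2-fold higher in ES and 3844 were lower, of 11130 with enough counts. Of the higher promoters, 3756 were low in both LZ and PD. Of the lower promoters, 2698 were high in both and 638 were high in LZ only. LZ counts enter both the class and the ratio here. The median log2 ratio was 0.20 with library totals, 0.47 with TMM factors and 0.06 with median-of-ratios size factors. The balance turned with quantile normalization, which gave 3716 higher and 4551 lower promoters with a median of -0.35, and was even after background subtraction, with 4485 higher and 4462 lower.

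Each of the 11132 promoters with at least 20 counts in some library was then assigned to the stage, if any, in which it was at least 2-fold above both others. With library totals, 1455 promoters were highest in LZ, 982 in PD and 4020 in ES, and 4675 had no such stage. Promoters highest in LZ had medians of 117 CPM in LZ, 13.9 in PD and 23.0 in ES. Those highest in PD had 39.6 CPM in LZ, 208 in PD and 39.5 in ES. Those highest in ES had 7.86 CPM in LZ, 2.90 in PD and 82.0 in ES. The number highest in PD changed most with the scaling, to 2156 with TMM factors and 3253 with median-of-ratios size factors. Under all 5 scalings, which include background subtraction and quantile normalization, 726 promoters were highest in LZ, 900 in PD and 2789 in ES. The subtraction took 8.39 CPM from ES, while promoters low in both LZ and PD had a median of 38.6 CPM in ES. A larger ES background was not tried. Those highest in ES with library totals had median counts of 13 in LZ and 14 in PD, below the minimum set for the highest library.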

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

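Quantile normalization, background subtraction, scaling to low or high promoters, the left-out rows, the moved boundary and every scaling of the stage counts were chosen after seeing the data. No paired analysis was possible because each stage has 1 library, and for the same reason no replicate could be left out. Planned settings that needed gene names or chromosomes (gene lists, housekeeping scaling, silent-family background, X-linked promoters) were not run. Counts of promoters at least 2-fold apart stayed within 1.5 times the reported count, except as follows. For PD against LZ, the higher promoters numbered 2668 with TMM factors, 3651 with median-of-ratios size factors, 608 at a 4-fold threshold and 4241 when scaled to promoters low in both libraries. The lower promoters numbered 2021 with median-of-ratios size factors, 5548 with no minimum count, 2237 at 4-fold, 1850 with quantile normalization and 1595 when scaled to promoters low in both. For ES against PD, the higher promoters numbered 3687 with quantile normalization and the lower 1961 at 4-fold. For ES against LZ, the lower promoters numbered 1921 at 4-fold. Promoters highest in PD numbered 2156 with TMM factors and 3253 with median-of-ratios factors, and those highest in LZ 968 with median-of-ratios factors. The 4-fold threshold and the missing minimum count change these counts by construction. TMM, median-of-ratios and low-promoter scaling change them by setting another ratio as unchanged, and quantile normalization by reshaping each distribution. For ES against PD, 137 promoters higher with library totals were lower after background subtraction and 325 after quantile normalization. Settings that shift all promoters together, or change only a threshold or minimum, could hardly turn a promoter in this way. Moving the boundary between low and high groups by 0.5 on the log2 scale gave 3313 to 4209 promoters high in both and 4850 to 5890 low in both. Correlations hardly moved with a minimum of 20 counts, which removed few promoters. LZ had the smallest total and so the widest counting error at a given level. Promoters with 0 counts numbered 108 in LZ, 56 in PD and 0 in ES as deposited, and 108, 283 and 10 after thinning to equal totals, so they do not follow depth alone.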

Other observations

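The sets of promoters and rows described first, and the test of differences between single libraries, were chosen after their values were seen, while the limits of the other tests were set before their results. A small set of promoters was strongly marked in LZ and far lower in PD. Within the LZ top 10%, 65 promoters were at least 16-fold lower in PD. Their median counts were 634 in LZ, 17 in PD and 114 in ES. Of these 65 promoters, 38 (58.5%, 95% Clopper-Pearson interval 45.6 to 70.6) lay in the lowest 25.1% of ES, against 18 of the 1050 other promoters in the LZ top 10% (1.71%, 1.02 to 2.70). The ES top 10% held 2 of the 65 and 85 of the 1050 others. The set was noticed in the plot of library pairs. What these loci are is not analysed here.

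Neighbouring locus numbers had weakly correlated marking. Over 5901 pairs of consecutive numbers, the Spearman rho of the level was 0.32 in LZ, 0.23 in PD and 0.10 in ES, while 100 draws of random pairs gave at most 0.04 in any library. The log2 ratio of PD to LZ had a rho of 0.05 over consecutive numbers, that of ES to PD 0.16 and that of ES to LZ 0.21. The last 140 rows of the table had medians of 2 counts in LZ, 2 in PD and 166 in ES, against 58, 60 and 884 in all other rows.

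More promoters were lower than higher in PD than in LZ when library totals set the scale (71.8% of those counted). Thinning PD to the LZ total left 71.7% lower. Random thinning keeps each promoter's expected share of its library, so it could hardly change this percentage and does not decide whether unequal depth contributes. The percentage did depend on the minimum count, at 64.7% with a minimum of 50 counts and 79.6% with none. The 1% most counted promoters held 6.73% of the LZ counts and 7.04% of the PD counts. A few promoters thus did not take a much larger share in PD. Leaving out this 1% of each library could hardly change the scale, and 72.3% were lower without it. The 10% most counted promoters held 39.0% of the LZ counts and 47.8% of the PD counts, and leaving them out was not tested. Fewer background counts in the PD library may account for part of the excess of lower promoters and remain open for the rest. After the median of the promoters low in both (8.46 CPM in LZ, 2.90 CPM in PD) was subtracted, 60.8% were lower. This lay between the limits of 60 and 75 set for deciding. Lower promoters then numbered 3226, against 3391 before, and higher promoters 2081, against 1332. The percentage thus fell mostly because more promoters were higher. A change of H3K4me3 with the stage is untested, as it cannot be told apart from enrichment that differed between these single immunoprecipitations.

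The ES profile departed from both spermatocyte profiles. Counting noise in LZ is argued against across all promoters. When each LZ count was assigned at random to 1 of 2 parts, the parts correlated with a rho of 0.96, against 0.22 between LZ and ES. The value of 0.96 spans the low and high groups together. It was not computed within promoters low in both, whose median was 14 counts in LZ. Duplicate reads would raise the value of 0.96, but LZ also correlated with the separate PD library at 0.78. Uniform background in ES, which cannot reorder promoters, is argued against for the ES top 10%. Of that top 10%, 61.3% was low in both LZ and PD, above the 47.9% of all promoters. The interval of 58.4 to 64.2 treats promoters as independent and may be too narrow. Uniform background may still raise the lowest ES promoters. With 1 library per stage, the stage cannot be told apart from other differences between the libraries. These include cell purity, nuclease digestion, immunoprecipitation or a different processing of the ES reads.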
